A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

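Total RNA from chemostat cultures of S. cerevisiae was labelled with biotin and hybridised to 6 Affymetrix Yeast Genome 2.0 arrays, per the labels. The deposited values are summarised probe set intensities on a linear scale, 1 column per array, as the range of the values shows. The program that the authors used to summarise and normalize the probes is not given in the sources used here. Samples were assigned to the control, NOX and AOX strains, 2 arrays each, by their titles.

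The table held 10928 probe sets. The array's annotation gave 7245 of them a name, and names were updated through Entrez identifiers to the R64 gene table. Of these, 5498 probe sets matched an S. cerevisiae gene with 1 symbol (5449 genes, of which 47 had over 1 probe set) and were tested. A further 1747 named probe sets matched no gene of that table, belong to another organism carried by the array and served as a measure of background. The remaining 3470 unnamed probe sets and 213 control or reporter probe sets were left out of the main test. Genomic coordinates are not printed, since the build behind the annotation was not named. Intensities were transformed as log2(value + 16), and fold changes are on this scale, which understates the change of dim genes. The medians of the arrays differed by up to 0.204 on that scale, above the limit of 0.1 set beforehand, so quantile normalization between arrays followed.

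Strains were compared with limma 3.58.1 in R 4.3.3, with a mean per strain over all 6 arrays (3 residual degrees of freedom, 2.77 prior degrees of freedom), lmFit and eBayes, and Benjamini-Hochberg adjustment over the 5498 probe sets at 0.05. Errors of fold changes are limma's standard errors with n = 2 arrays per strain, and errors of group levels are SDs. The lists were tested with camera at a preset correlation of 0.01, with 1 probe set per gene, the brightest, and adjustment over the 34 lists. An estimated correlation in its place left no list called in any comparison. That form rests on the 3 residual degrees of freedom and has little power here. Not passing it therefore does not show that a list was unchanged, while the preset correlation remains an assumption. The self-contained test fry was also run. The 34 lists were written before the data were examined, from general knowledge of yeast pathways, and 1 listed gene was not matched. Genes counted as rising or falling in a list passed the threshold over all probe sets. Where a gene was below the 95th percentile of the other-organism probe sets on both arrays of a strain, it is described as not well above background there, and its fold is a lower bound, computed against that percentile. For genes under the percentile on 1 array of the lower strain between AOX and NOX, the fold was bounded in the same way.

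The genes named were set by a rule made before the data were examined. It took, per comparison, the 10 probe sets with the largest rise and the 10 with the largest fall among those called without overlap, up to 4 members of each called list with the smallest adjusted p, and a fixed set for the plasmid and for NADH, ethanol and glycerol metabolism. The fixed set was URA3, TPI1, NDI1, NDE1, NDE2, GPD1, GPD2, GUT2, ADH1, ADH2, PDC1, ALD6, ACS1, CIT1, HAP4, HXT1 and HXT7. Other members of the lists, and genes called in both comparisons, were named after their values were seen. The comparisons of NOX and AOX with control share their controls, so 100 simulations of unchanged groups were run. The control arrays were simulated too, with the spread pooled over the strains, which is wider than their own. The simulations gave the values that sharing produces at that pooled spread, not at the spread of the measured controls.

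The fit was tested on simulated data with 200 of 5498 probe sets changed in the NOX against control comparison. It recovered 90% of 50 changes of 0.5 log2, 96% of 50 changes of 1 and all of 50 changes each of 2 and 3, and 9 of 202 calls were false. The simulation gave each probe set the same spread in all strains and let probe sets vary independently. In the measured arrays the spread differed by strain and replicate differences were related across probe sets, so these rates need not hold for them. The alternatives tried were the deposited values without quantile normalization, median scaling on the S. cerevisiae or the other-organism probe sets, leaving out dim probe sets, pseudocounts of 1 and 64, a variance trend with robust priors, a threshold of 0.01 or 2-fold, a fit of only the arrays compared, a block for the replicate number, each array left out in turn, and for the lists an estimated correlation and fry. Where an array was left out, the remaining array of that strain was assumed to vary like those of the other strains.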

Results

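Messenger RNA was measured in chemostat cultures of the laboratory yeast strain CEN.PK113-7D, grown in minimal medium with 10 g/L glucose at the critical dilution rate, which is the growth rate at which overflow to ethanol sets in. A control strain carried the empty plasmid pYX212. The NOX strain carried the same plasmid with NOX, known as a water-forming NADH oxidase of the cytosol, and the AOX strain carried it with AOX, the alternative oxidase of mitochondria. Each of the 3 strains was represented by 2 Affymetrix Yeast Genome 2.0 arrays, 6 arrays in all, and the number of arrays limits the precision of every value. The median deposited intensity over the S. cerevisiae probe sets lay between 511 and 543 on the 6 arrays. Between 94.7% and 96.9% of these probe sets were brighter than the 95th percentile of the probe sets for another organism on the same array. On NOX replicate 1 the hybridisation controls averaged 11.08 on the log2 scale, against 9.52 to 9.96 on the others, and ribosomal RNA probe sets averaged 5.11, against 6.03 to 7.53. The labels do not say whether replicate arrays came from separate cultures, so p-values measure the spread between these samples, which may be technical. No probe set for either transgene was identified here, so the transgenes themselves were not measured. The labels give no dilution rate in numbers, so whether the 3 strains grew at the same rate is not known. A difference in growth rate between the strains could not be told apart from an effect of the transgenes.

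The first comparison asked how gene expression differed when the cells carried an NADH oxidase. The largest rise in NOX was that of FDH1, which encodes a formate dehydrogenase. Its probe set was not well above background on the control arrays and was at least 9.14-fold higher in NOX (log2 8.96 ± 0.03 against 5.59 ± 0.08, SD, n = 2 each; limma adjusted p = 0.000331). ADH2, the alcohol dehydrogenase that oxidises ethanol, rose by 1.98 on the log2 scale (SE 0.08, a 3.93-fold rise; adjusted p = 0.000569). RGI2, a gene induced in respiratory growth, rose by 1.85 (SE 0.05), SPG4, a stationary phase gene, by 1.94 (SE 0.05), and the small heat shock gene HSP26 by 1.56 (SE 0.04). The largest fall was that of PTR2, the transporter of small peptides, which fell by 2.11 (SE 0.14; adjusted p = 0.00277).

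Further rises in NOX were those of SIP18 (1.5), PRR2 (1.21), GCY1, a glycerol dehydrogenase (1.18), and ATO3, a plasma membrane protein of ammonium export (1.17). YMR175W-A rose by at least 1.38-fold, but it overlaps SIP18 in the genome and its value is uncertain. Among the falls, FBP1, the fructose bisphosphatase of gluconeogenesis, changed by -1.05 (SE 0.09), the glycerol importer gene STL1 by -0.98 (SE 0.05) and ICL1, the isocitrate lyase of the glyoxylate cycle, by -0.65 (SE 0.05). SRY1 (-0.95), the amino acid permease gene TAT1 (-0.83), the polyamine transporter genes TPO1 (-0.77) and TPO4 (-0.75), the mannosyltransferase gene MNN1 (-0.72) and YNL134C (-0.69) also fell. In all, limma called 204 of 5498 probe sets at a Benjamini-Hochberg adjusted p below 0.05, 154 higher and 50 lower in NOX, and 19 of them differed by 2-fold or more. The count changed when single arrays were left out: it was 17 without control replicate 1, 14 without control replicate 2, 111 without either AOX replicate and 1453 without NOX replicate 2, then 739 higher and 714 lower. Of the 31 called genes named by rule in NOX, most lost their call without control replicate 1, and most also without control replicate 2. In these fits 0 of the 31 moved their log2 change by over 1.5 times. That outcome was close to fixed, since a call already requires replicates that differ little relative to the change.

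By group, the general stress response list rose in NOX: 13 of its 35 measured genes rose, 1 fell and 21 did not pass (19 and 1, adjusted over the list alone). The camera test gave an adjusted p of 2.77e-09, but adjusted p = 0.432 with an estimated correlation. HSP26 and SIP18 were joined by the chaperone genes HSP42 (0.55) and SSE2 (0.58). In the list of the pentose phosphate pathway and NADPH supply, 3 of 17 genes rose and none fell (5 and 0, adjusted over the list alone; camera adjusted p = 0.0104, and adjusted p = 0.432 with an estimated correlation). These were NQM1, a transaldolase paralog (0.74), YEF1, an NADH kinase (0.63), and ALD6, the cytosolic aldehyde dehydrogenase (0.30). The fatty acid beta-oxidation list was called as higher, with 1 of 19 genes rising on its own, the peroxisomal transporter gene PXA1 (0.59), and 8 rising when adjusted over the list alone (camera adjusted p = 0.00349, and adjusted p = 0.432 with an estimated correlation). Other members of it were YAT2 at 0.24 and CTA1, the peroxisomal catalase, at 0.43, neither past the threshold. Among 30 meiosis and sporulation genes, 3 rose, SPS1 (0.62), GAS4 (0.54) and SPO11 (0.42), and 3 did so when adjusted over the list alone (camera adjusted p = 0.00067, and adjusted p = 0.608 with an estimated correlation). Over the alternatives SPS1 ranged from 0.38 to 0.78, GAS4 from 0.34 to 0.65 and SPO11 from 0.30 to 0.49. SPS1 and SPO11 were not called with the replicate number as a block. Without NOX replicate 1 this list had a mean of 0.13 in place of 0.21 and an adjusted p of 0.0507, and fry gave 0.164. On the deposited values and with median scaling on S. cerevisiae probe sets the mean was 0.11.

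A further 5 lists were called as lower in NOX by small means. The 62 ribosome biogenesis genes had a mean log2 change of -0.08 (camera adjusted p = 0.00067, and adjusted p = 0.529 with an estimated correlation), and RLI1 stood at -0.22. The 60 amino acid biosynthesis genes had a mean of -0.08 (camera adjusted p = 0.00067, and adjusted p = 0.432 with an estimated correlation), although GDH2, the NAD-dependent glutamate dehydrogenase, rose by 0.46. The 66 mitochondrial ribosomal protein genes had a mean of -0.05 (camera adjusted p = 0.0313, and adjusted p = 0.608 with an estimated correlation). The 27 cell cycle genes had a mean of -0.08 (camera adjusted p = 0.0345, and adjusted p = 0.529 with an estimated correlation). The 26 mitochondrial carrier genes had a mean of -0.10 (camera adjusted p = 0.0487, and adjusted p = 0.754 with an estimated correlation), among them AGC1 at -0.37. No gene of these lists fell past the threshold over all genes, and adjusted over the list alone 3 carrier genes fell and none of the others. Without NOX replicate 2 the adjusted p was 0.372 for ribosome biogenesis (mean -0.05), 0.525 for mitochondrial ribosomal proteins (mean -0.02), 0.448 for the cell cycle, 0.314 for the pentose phosphate list and 0.0577 for beta-oxidation. Without NOX replicate 1 it was 0.991 for the carriers, whose mean was then -0.01 (-0.19 without NOX replicate 2), and without either AOX replicate it was 0.0506. Without control replicate 2 it was 0.0611 for the carriers and for the cell cycle, and without control replicate 1 it was 0.0624 for mitochondrial ribosomal proteins. The cell cycle call also ended on the deposited values (0.053), with median scaling on S. cerevisiae or other-organism probe sets (0.0551 and 0.0542) and with fry (0.148). The carrier call ended on the deposited values (0.0688), with median scaling on S. cerevisiae probe sets (0.0551), without dim probe sets (0.0534) and with fry (0.403). With the other-organism scaling the mean of the cell cycle list was -0.04. The mean of the mitochondrial ribosomal proteins was -0.08 without NOX replicate 1, -0.09 on the deposited values and -0.08 with median scaling on S. cerevisiae probe sets. By fry, mitochondrial ribosomal proteins (0.27) and ribosome biogenesis (0.187) did not pass.

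The glyoxylate cycle and gluconeogenesis list was not called in NOX (camera adjusted p = 0.367), and its members went both ways. Of 12 genes, 4 rose, ICL2 (0.92), ACS1, the acetyl-CoA synthetase of non-fermentative growth (0.76), MDH2 (0.69) and the lactate transporter gene JEN1 (0.34), while FBP1, ICL1 and PCK1 (-0.50) fell (5 and 3, adjusted over the list alone). Without control replicates 1 and 2 the adjusted p was 0.129 and 0.126 for ACS1, 0.0715 and 0.0737 for FBP1 and 0.0751 and 0.091 for ICL1. The lists of respiratory complexes III and IV (camera adjusted p = 0.94), the ATP synthase (0.367), NADH dehydrogenases and redox shuttles (0.777) and the TCA cycle (0.738) did not pass either. For the last 2 of these lists the mean and the median differed in sign, with means of 0.09 and 0.02 and medians of -0.02 and -0.03. Nearer the threshold were the iron regulon, with 3 of 27 genes higher, and the retrograde targets (camera adjusted p = 0.0503 each), and glycolysis (0.0651). By fry, retrograde targets (adjusted p = 0.00237), pyruvate, ethanol and acetate metabolism (0.0278) and oxidative stress defence (0.0278) passed as higher, and mitochondrial import (0.0286) as lower. NDI1 and NDE1, NADH dehydrogenases of mitochondria, differed by -0.02 and -0.03, and NDE2 by 0.63 (SE 0.12; adjusted p = 0.0517). The fermentation genes PDC1 and ADH1 differed by 0.06 and 0.02, CIT1 by 0.01, HAP4 by -0.01, GUT2 by 0.14 and TPI1 by 0.03, none past the threshold. GPD2, a glycerol 3-phosphate dehydrogenase that oxidises NADH, differed by 0.95 with an SE of 0.39 (adjusted p = 0.228).

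The second comparison asked the same of the alternative oxidase. FIT2 and FIT3, cell wall proteins of siderophore iron uptake, rose most in AOX, by 4.17 (SE 0.10, 18.0-fold) and 3.54 (SE 0.15, 11.6-fold). TIS11, known to degrade messenger RNA of iron proteins when iron is short, was at least 6.32-fold higher, and the ferric reductase FRE5 at least 3.81-fold. The siderophore transporter SIT1 rose by 2.76 (SE 0.13) and FET3, the oxidase of high-affinity iron uptake, by 2.03 (SE 0.07). The limma adjusted p was 3e-05 for FIT2, TIS11 and FRE5 and 0.000296 for FIT3. The largest fall was that of ZRT1, the high-affinity zinc transporter, which fell by 2.14 (SE 0.08, adjusted p = 0.000229).

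Of the 27 measured iron regulon genes, 19 rose in AOX, none fell and 8 did not pass (23 rose and 3 fell, adjusted over the list alone). The mean log2 change was 1.16 and the median 0.70 (camera adjusted p = 1.63e-27, and adjusted p = 0.131 with an estimated correlation).

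**Figure D1:**
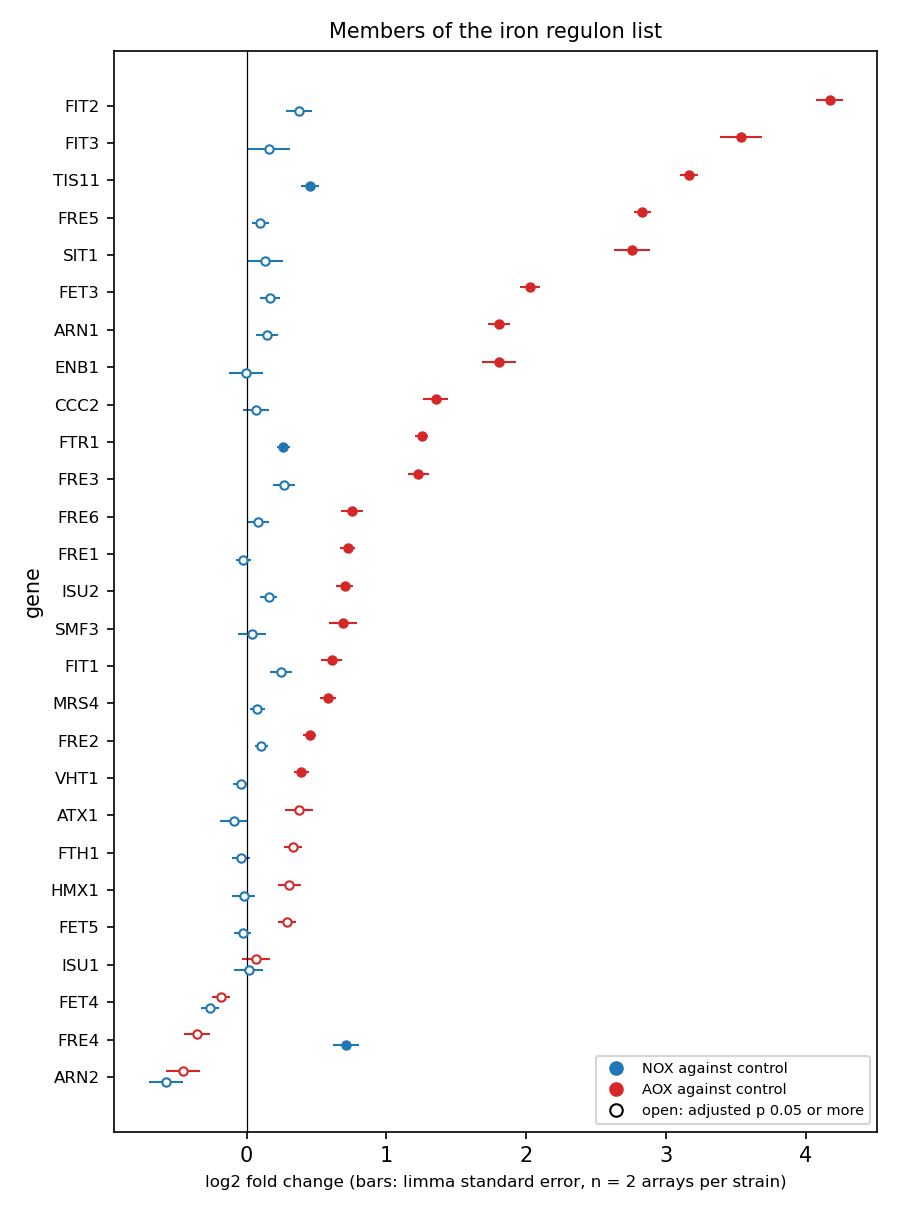
Log2 fold change against the control strain (x axis) of each of the 27 measured genes of the iron regulon list (y axis), for NOX in blue and AOX in red, with limma standard errors as bars and n = 2 arrays per strain. Filled points have an adjusted p below 0.05: 19 AOX points are filled and all lie to the right of 0, with FIT2 at 4.17, while 3 NOX points are filled.

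Other rises in AOX were those of CTL1, an RNA triphosphatase (2.10), and TKL2, a transketolase (1.83). HXT13, of the hexose transporter family, was at least 1.59-fold and 1.71-fold higher on its 2 probe sets, which may also bind near-identical family members, so that its value is uncertain. The general stress response list rose, with 24 of 35 genes higher and none lower (27 and 0, adjusted over the list alone; camera adjusted p = 3.08e-26, and adjusted p = 0.126 with an estimated correlation). Examples were YGP1 (1.30), PGM2 (0.86), SPI1 (0.80) and HSP26 (0.80). In the glycerol list, 4 of 12 genes rose and 1 fell (5 and 1, adjusted over the list alone; camera adjusted p = 0.000941, and adjusted p = 0.162 with an estimated correlation). GPP2 (0.89), GPD1 (0.62), which encode the enzymes that form glycerol, YPR1 (0.48) and STL1 (0.45) rose, whereas DAK2, a dihydroxyacetone kinase, was at least 1.61-fold lower. The glycolysis list was higher by a mean of 0.13, with 2 of 16 genes rising, ENO1 (0.54) and TDH1 (0.51), and 2 also when adjusted over the list alone (camera adjusted p = 0.00122, and adjusted p = 0.481 with an estimated correlation). The same 2 genes rose in NOX, where the list had a mean of 0.09 and did not pass (camera adjusted p = 0.0651). It was not called between AOX and NOX either (mean 0.04, camera adjusted p = 0.378). Many glycolytic probe sets lay near the upper end of the intensity scale, where changes may be compressed, which was not tested.

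In the glyoxylate and gluconeogenesis list, 8 of 12 genes fell in AOX and none rose (10 and 0, adjusted over the list alone; camera adjusted p = 3.01e-13, and adjusted p = 0.0692 with an estimated correlation). PCK1, which starts gluconeogenesis, changed by -1.20 (SE 0.07), the succinate carrier gene SFC1 by -0.85, ICL2 by -0.80 and the malate synthase gene MLS1 by -0.73. In the fatty acid beta-oxidation list, 8 of 19 genes fell and none rose (15 and 0, adjusted over the list alone; camera adjusted p = 3.07e-14, and adjusted p = 0.0692 with an estimated correlation), among them CTA1 (-1.06), POX1 (-0.86), FOX2 (-0.77) and FAA2 (-0.60). Of 24 genes under nitrogen catabolite repression, 5 fell (9 fell and 1 rose, adjusted over the list alone; camera adjusted p = 4.85e-05, and adjusted p = 0.139 with an estimated correlation), with PUT1, the proline oxidase, at -1.10, the ammonium permease gene MEP2 at -0.81, DAL3 at -0.70 and DAL2 at -0.59. The TCA cycle list had a mean of -0.08 with no gene past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.481 with an estimated correlation), and its adjusted p was 0.0835 without AOX replicate 2 and 0.102 with fry. Outside these lists ATO3 (-1.74), ADH2 (-1.31), RGI2 (-1.26), the metalloreductase gene FRE7 (-1.02), the aromatic aminotransferase gene ARO9 (-0.98) and ATO2 (-0.97) fell.

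**Figure D2:**
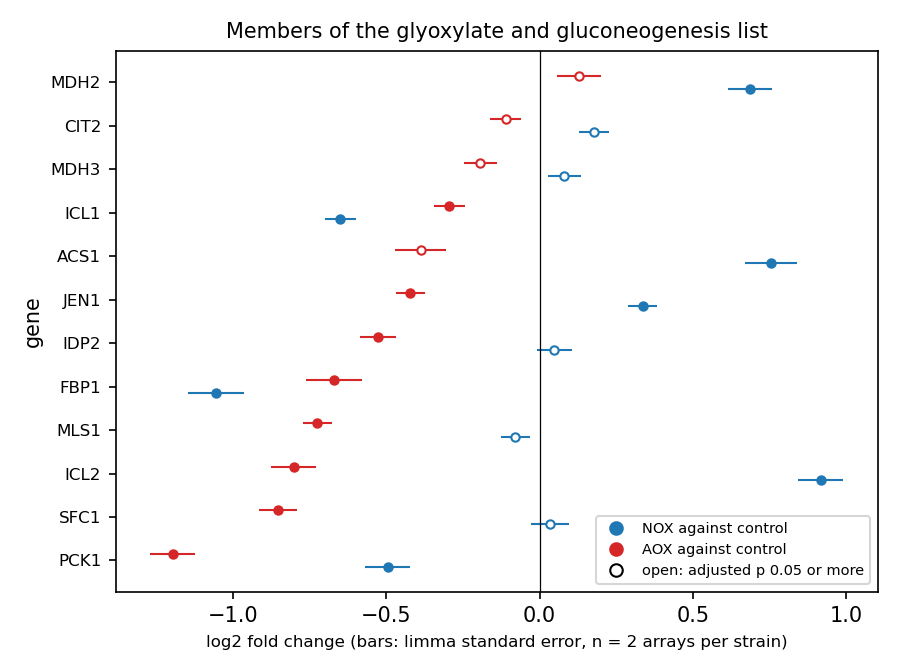
Log2 fold change against the control strain (x axis) of each of the 12 genes of the glyoxylate and gluconeogenesis list (y axis), for NOX in blue and AOX in red, with limma standard errors as bars and n = 2 arrays per strain. Filled points have an adjusted p below 0.05: in AOX 8 genes are filled and all lie to the left of 0, while in NOX 4 filled points lie to the right and 3 to the left.

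In all, limma called 197 of 5498 probe sets in AOX, 140 higher and 57 lower, and 32 differed by 2-fold or more. URA3, the marker gene of the plasmid, changed by -0.68 in AOX (SE 0.06, adjusted p = 0.00246, and 0.0554 without control replicate 2) and by -0.29 in NOX (SE 0.06, adjusted p = 0.0517). NDI1 differed by -0.25 (adjusted p = 0.0857), NDE1 by -0.08, NDE2 by 0.38, ACS1 by -0.39 (adjusted p = 0.0874), HAP4 by -0.11, GUT2 by 0.05, ALD6 by -0.03, CIT1 by -0.04, TPI1 by 0.05 and PDC1 and ADH1 by 0.03 and -0.02, none past the threshold. GPD2 differed by 0.02 with an SE of 0.39. The lists of respiratory complexes III and IV (camera adjusted p = 0.631), the ATP synthase (0.418), NADH dehydrogenases and redox shuttles (0.249), hexose transport (0.277), hypoxic genes (0.89) and heme and ubiquinone (0.277) did not pass. By fry, hexose transport alone among these passed (adjusted p = 0.00951), with 3 of 17 genes higher. For complexes III and IV the mean was 0.01 and the median -0.04. The count was 62 without control replicate 1, 52 without control replicate 2, 89 and 78 without AOX replicates 1 and 2, and 364 without either NOX replicate. Of the 40 called genes named by rule in AOX, 31 and 28 kept their call without control replicates 1 and 2.

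The direct comparison of AOX with NOX tested whether the 2 transgene strains differed. ADH2 was lower in AOX than in NOX by a log2 difference of -3.29 (SE 0.08, adjusted p = 3.68e-05), RGI2 by -3.11 (SE 0.05), ATO3 by -2.92 (SE 0.14) and ZRT1 by -2.31 (SE 0.08). FIT2 was higher in AOX by 3.80 (SE 0.10), FIT3 by 3.38 (SE 0.15), SIT1 by 2.63 (SE 0.13), PTR2 by 2.14 (SE 0.14), CTL1 by 1.93 (SE 0.09) and FET3 by 1.86 (SE 0.07). FDH1, under the background percentile on 1 of the 2 AOX arrays, was at least 9.42-fold lower in AOX, and TIS11, under it on 1 of the 2 NOX arrays, at least 6.40-fold higher. FRE5 was at least 4.07-fold higher, and HXT13 at least 1.70-fold and 1.83-fold on its 2 probe sets. PUT1 (-1.82), ICL2 (-1.72), SIP18 (-1.64), PRM5 (-1.63) and ARO9 (-1.53) were also lower in AOX.

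**Figure D3:**
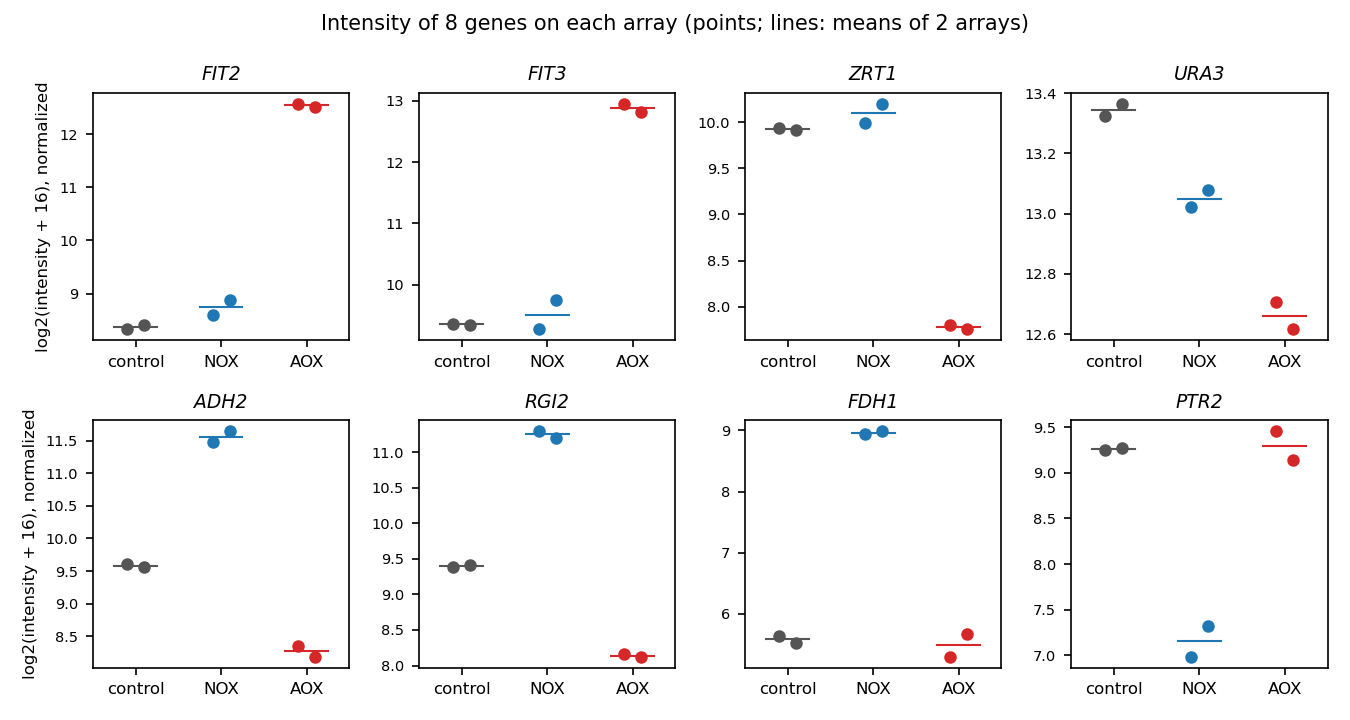
Normalized log2(intensity + 16) (y axis) of 8 genes on each of the 6 arrays, by strain (x axis); points are single arrays and lines are means of 2 arrays, and each panel has its own scale. FIT2 and FIT3 are higher and ZRT1 is lower on both AOX arrays, FDH1 is higher and PTR2 lower on both NOX arrays, and ADH2 and RGI2 lie above the control in NOX and below it in AOX.

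By group, 22 of 27 iron regulon genes were higher in AOX than in NOX and 1 lower, the reductase FRE4 (23 and 1, adjusted over the list alone; camera adjusted p = 1.9e-20, and adjusted p = 0.196 with an estimated correlation). In the glyoxylate list, 10 of 12 genes were lower, among them ACS1 (-1.14), SFC1 (-0.89) and JEN1 (-0.76), and ICL1 was higher (10 lower and 2 higher, adjusted over the list alone; camera adjusted p = 1.07e-07, and adjusted p = 0.153 with an estimated correlation). In the beta-oxidation list, 12 of 19 were lower, with CTA1 at -1.49, PXA1 at -1.23, POX1 at -1.03 and FOX2 at -0.94 (15, adjusted over the list alone; camera adjusted p = 7.21e-13, and adjusted p = 0.128 with an estimated correlation). In the general stress list, 14 of 35 were higher, such as YGP1 (1.24) and PGM2 (0.72), and 3 were lower, including HSP26 at -0.76 (18 and 3, adjusted over the list alone; camera adjusted p = 0.000269, and adjusted p = 0.353 with an estimated correlation). Of 24 nitrogen catabolite genes, 8 were lower, with GDH2 at -0.72, MEP2 at -0.63 and DAL3 at -0.49 (9 lower and 1 higher, adjusted over the list alone; camera adjusted p = 0.000153, and adjusted p = 0.196 with an estimated correlation). In the zinc list, ZRT1 and IZH4 (-0.86) were lower, IZH2 (0.30) was higher and 8 of 11 did not pass (3 lower and 1 higher, adjusted over the list alone; camera adjusted p = 0.0278, and adjusted p = 0.52 with an estimated correlation). Of 9 retrograde response targets, CIT3 (-1.02), PDH1 (-0.49) and CIT2 (-0.29) were lower (4, adjusted over the list alone; camera adjusted p = 0.00465, and adjusted p = 0.29 with an estimated correlation).

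The remaining called lists differed less between AOX and NOX. Of 60 amino acid biosynthesis genes, 8 were higher, such as ARG1 (0.34), and 4 lower, such as GDH3 (-1.32) and BAT2 (-0.84) (15 and 4, adjusted over the list alone; camera adjusted p = 0.004, and adjusted p = 0.342 with an estimated correlation). In the pentose phosphate list, TKL2 (1.82) was 1 of 2 higher genes and IDP2 (-0.58), YEF1 (-0.69) and NQM1 (-0.41) were among 5 lower ones (2 and 5, adjusted over the list alone; camera adjusted p = 0.0386, and adjusted p = 0.342 with an estimated correlation). Of 27 ergosterol genes, ERG28 (-0.41) and ERG7 (-0.26) were lower and ARE2 (0.53) was higher (3 and 1, adjusted over the list alone; camera adjusted p = 0.0197, and adjusted p = 0.353 with an estimated correlation). Cytosolic ribosomal proteins were higher by a mean of 0.04, with none of 127 genes past the threshold (0, adjusted over the list alone; camera adjusted p = 0.0152, and adjusted p = 0.353 with an estimated correlation). In ribosome biogenesis, UTP15 (0.26), HAS1 (0.26) and NOP58 (0.21) were higher among 62 genes (0, adjusted over the list alone; camera adjusted p = 0.0339, and adjusted p = 0.58 with an estimated correlation). None of these genes was called with median scaling on other-organism probe sets or with the replicate block. RNR1 (0.27) was higher among 27 cell cycle genes (0, adjusted over the list alone; camera adjusted p = 0.00431, and adjusted p = 0.326 with an estimated correlation). SPS1 (at least 1.6-fold) and SPO11 (-0.33) were lower among 30 meiosis genes (1, adjusted over the list alone; camera adjusted p = 0.0107, and adjusted p = 0.63 with an estimated correlation). SPO11 was not called on the deposited values, with either other pseudocount, with the other variance model or with the replicate block. Several of these calls ended without 1 array. Without NOX replicate 2 the adjusted p was 0.136 for the cell cycle, 0.148 for cytosolic ribosomal proteins, 0.25 for ergosterol (mean -0.04), 0.203 for the pentose phosphate list, 0.575 for ribosome biogenesis (mean 0.03, against 0.10 without NOX replicate 1) and 0.172 for the zinc list. Without AOX replicate 2 it was 0.0627 for cytosolic ribosomal proteins, 0.0624 for ergosterol, 0.109 for ribosome biogenesis and 0.0817 for the pentose phosphate list. The meiosis list had an adjusted p of 0.237 without NOX replicate 1 (mean -0.07) and 0.249 without AOX replicate 1 (mean -0.06), with means of -0.22 and -0.23 without the other replicate of each strain, the zinc list 0.0804 without AOX replicate 1, and the pentose phosphate list 0.0577 without either control replicate and 0.0589 without NOX replicate 1. The mean of the pentose phosphate list, -0.02, lay between -0.04 and -0.00089 over these alternatives, and that of the amino acid list, 0.06, was 0.03 without NOX replicate 1 and 0.10 and 0.09 on the deposited values and with median scaling on S. cerevisiae probe sets. On the deposited values, with median scaling on S. cerevisiae probe sets and with median scaling on other-organism probe sets, the adjusted p was 0.161, 0.219 and 0.383 for cytosolic ribosomal proteins, 0.151, 0.101 and 0.0965 for ergosterol and 0.0941, 0.0783 and 0.0965 for the pentose phosphate list. The mean of the cytosolic ribosomal proteins was then 0.04, 0.04 and 0.0091, and that of the ergosterol list -0.03, -0.03 and -0.06. The scaling on other-organism probe sets also gave 0.0512 for ribosome biogenesis and 0.0798 for meiosis, whose mean was -0.08 on the deposited values and -0.09 with median scaling on S. cerevisiae probe sets, and fry gave 0.209 and 0.286 for these.

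In all, 461 probe sets differed between AOX and NOX, 220 higher and 241 lower in AOX, and 65 by 2-fold or more. A fit of only these 4 arrays, without the narrower spread of the controls, called 202. GPD1 was higher in AOX by 0.41 (SE 0.05, adjusted p = 0.0067), and ALD6 (-0.33, adjusted p = 0.0146) and URA3 (-0.39, adjusted p = 0.0122) were lower. NDI1 differed by -0.23, NDE1 by -0.05, NDE2 by -0.25, GPD2 by -0.93 (SE 0.39), HAP4 by -0.09 and PDC1 by -0.03, none past the threshold. HXT1 was not well above background in any strain, and HXT7, whose probe set may bind near-identical hexose transporter genes, differed by 0.03 or less between any 2 strains. The count was 202 without either control replicate, 158 and 171 without AOX replicates 1 and 2, and 1467 without NOX replicate 2. Without AOX replicate 2 the call was kept by 39 of the 57 called genes named by rule for this comparison, and without AOX replicate 1 by 42.

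Of the genes called against control in NOX or AOX, 64 probe sets were called in both. This overlap was 5 without control replicate 1 and 5 without control replicate 2, 26 and 23 without AOX replicates 1 and 2, and 110 and 186 without NOX replicates 1 and 2. Higher in both were 33, among them TDH1, ENO1, DDR2, HSP42 and HSP26, where independent lists would share 3.92, and lower in both were 6, among them FBP1, ICL1, PCK1 and TAT1, where independent lists would share 0.518. A further 14 were higher in NOX and lower in AOX (1.6 for independent lists), such as ADH2, RGI2, ATO3, PUT1 and ICL2, and 11 were lower in NOX and higher in AOX (1.27 for independent lists), such as STL1, OPT2 and EEB1. The latter 11 include HMS1, which was not well above background in control or NOX, and the 33 include SWC7, which was not well above background in any strain, so that their directions are uncertain and 62 of the 64 remain without them. The counts for independent lists do not allow for the shared controls. Simulated unchanged groups with shared controls gave 0.01 probe sets called in both on average. Almost nothing is called in unchanged groups, so this value is no measure of what the shared controls add to the overlap. Changed groups with unrelated changes were not simulated. The 2 fold changes had the same sign in 63.4% of probe sets, against 66.8% in the simulation of unchanged groups, whose controls had the pooled spread. Across genes, which are not independent replicates, the fold changes correlated with r = 0.18. Unchanged groups gave 0.503, or 0.15 when the controls were simulated with their own spread, so that the value lay below one and above the other. The covariance was 0.00772, against 0.00373 for unchanged groups and 0.000662 when the controls were simulated with their own spread. The difference from the former, 0.00399, became -0.000661 without control replicate 1, -0.00241 without control replicate 2 and -0.000701 without AOX replicate 2. Leaving out an array also changed the simulated value. A split of the controls would leave 1 array for each comparison and was not run, so part of any excess may come from the shared controls. Over the 3 strains together, the moderated F-test called 412 probe sets, and 158 without control replicate 2.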

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

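The test of a culture difference in the iron regulon was chosen after the result was seen, and the others before it.

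NOX and AOX differed in the direction of their change for 25 genes, each called against control in both strains, with opposite signs. All 25 were also called in the direct limma test of AOX against NOX. This follows from the opposite calls, since that difference adds both changes at the same standard error. Of the 25 genes, 14 were higher in NOX and lower in AOX. Their AOX minus NOX log2 differences were -3.29 for ADH2, -3.11 for RGI2, -2.92 for ATO3, -1.82 for PUT1, -1.72 for ICL2, -1.63 for PRM5, -1.47 for ATO2, -1.40 for PDR12, -1.36 for QDR2, -1.23 for PXA1, -1.18 for AQY2, -1.15 for YIG1, -1.09 for TIP1 and -0.76 for JEN1. The 11 that were lower in NOX and higher in AOX differed by 0.70 for PRM7, 0.87 for FSH1, 0.99 for MNN1, 1.02 for WSC4, 1.07 for TPO2, 1.15 for YNL134C, 1.18 for YBL029W, 1.29 for HMS1, 1.42 for OPT2, 1.43 for STL1 and 1.65 for EEB1. QDR2 was not well above background in AOX and was at least 1.92-fold lower there. HMS1 was not well above background in control or NOX, so that its direction in NOX is uncertain and 24 genes remain without it, 10 of them higher in AOX, and it was at least 1.33-fold higher in AOX than in NOX. The calls against control depended on single arrays: without control replicates 1 and 2 there were 2 and 3 genes called with opposite signs, all higher in NOX, without AOX replicates 1 and 2 there were 14 and 13, and without NOX replicates 1 and 2 there were 50 and 72.

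Among probe sets outside the comparisons, some stood higher than on the control arrays. The control probe sets for TDH1, 5-prime and middle, were higher by 0.83 and 1.06 in NOX and by 0.83 and 0.99 in AOX. The 3-prime set stood at 0.43 and 0.47 and a second middle set at 0.04 and 0.03, neither called. Of 3470 unnamed probe sets, 4 were called higher and 3 lower in AOX. Of the higher ones, 1 stood above the background percentile on control and AOX arrays and differed by 0.83. The fitted difference of another was 2.07, at least 2.5-fold over the percentile in the control. The other 2, with fitted differences of 0.96 and 0.67, were under the percentile on both control arrays and on 1 and 2 AOX arrays, so no fold is given for them. Of the lower ones, 1 differed by -0.78, and the other 2, under the percentile in AOX, were at least 1.53-fold and 1.39-fold lower.

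Of 27 iron regulon genes, 19 rose in AOX (camera adjusted p = 1.63e-27, and adjusted p = 0.131 with an estimated correlation). Array scaling is argued against, since the medians of the arrays differed by only up to 0.204, far less than the list mean. Other scalings could therefore move that mean little, and its lowest value over 3 of them was 1.15. A single deviating array is argued against by a lowest mean of 1.14 with each of 6 arrays left out. A difference between the cultures other than the transgene, such as in medium iron, cannot be told apart from it: 19 of 19 risen genes were higher on both AOX arrays than on the 4 others, which either would give.

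The replicate differences of NOX and AOX were related across genes, which are not independent replicates, with opposite signs (r = -0.60). The correlation was -0.618 among the brighter 2749 probe sets, so the relation was not confined to dim ones. However, the 95th percentile of the other-organism intensities also differed in opposite directions. It was 27.4 and 35.5 on NOX replicates 1 and 2, and 43.9 and 31.3 on AOX replicates 1 and 2. A difference between arrays that goes with background and reaches bright probe sets is therefore not excluded. Without NOX replicate 1 the NOX comparison gave 264 calls. That fit no longer holds the spread between the NOX replicates, and AOX against control, whose arrays were unchanged, also gained calls in it. The count therefore cannot decide whether NOX replicate 1 alone carried the NOX calls. Of the 31 called genes named by rule in NOX, 0 moved their log2 change by over 1.5 times without that array. A call already requires NOX replicates that differ little relative to the change, so that outcome was close to fixed. It cannot decide whether the size of these changes rested on that array. What the replicates share stays open, and no biological explanation was tested.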

How the results depend on the processing

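The crossed block, the array weights and the controls simulated with their own spread were chosen after seeing the data, and the other tests before. Signal over background limited dim genes: 5264 of 5498 probe sets lay above the background percentile. Over the 3 scalings, the filter on dim probe sets, both other pseudocounts and the other variance model, the gene counts stayed within 1.5 times: 179 to 233 for NOX, 178 to 213 for AOX and 405 to 491 for AOX against NOX. Called lists kept their call in 318 of 403 comparisons with an alternative and named called genes in 1607 of 1787, the others kept their direction without passing, and none reversed. Among named genes not called, 68 of 1159 comparisons passed and 25 changed sign.

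An adjusted p under 0.01 gave 76, 115 and 195 probe sets for NOX, AOX and AOX against NOX, and a 2-fold minimum 19, 32 and 65, being stricter by construction. Fitting only the 4 arrays compared gave 111, 364 and 202. That fit has fewer degrees of freedom and takes its spread from the strains compared alone. The SD of the replicate difference was 0.0517 in control, 0.203 in NOX and 0.137 in AOX. The larger count for AOX against NOX in the main fit thus rests in part on the narrow spread of the controls. Array weights gave 501 for AOX and 246 for AOX against NOX, and the cause was not tested. With estimated correlation, camera called 0, 0 and 0 lists, where fry called 8, 11 and 16, and at an unadjusted p under 0.05 limma had 1224, 753 and 1251 probe sets. Scaling on other-organism probe sets left 9 lists for AOX against NOX, and the cause was not tested.

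Replicate numbers do not pair the arrays: their differences correlated by 0.116, -0.207 and -0.60 between strains. With the replicate number as a block the counts were 79, 124 and 237, and 229 among the 3 strains, with fewer degrees of freedom. With the AOX numbers exchanged, the block gave 365 for NOX.

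With each array left out, the counts ranged from 14 to 1453 for NOX, 52 to 364 for AOX, 158 to 1467 for AOX against NOX and 158 to 1466 among the 3 strains. The lists ranged from 4 to 10, 8 to 10 and 9 to 16. The lowest gene counts for both comparisons with control came without control replicate 2 and the highest for NOX without NOX replicate 2, where the lone array is assumed to vary like the other groups. The control arrays lay closest together (SD of the difference 0.0517, against 0.203 in NOX and 0.137 in AOX).

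The shared response, the excess covariance of 0.00399, was 0.00262 with median scaling, 0.00317 without dim probe sets and 0.00706 with the controls simulated with their own spread. It ranged from -0.00241 to 0.00898 with arrays left out, and turned negative without control replicate 1 (-0.000661), control replicate 2 (-0.00241) and AOX replicate 2 (-0.000701). Without a control array the subtracted value was simulated with 1 control array and the spread of NOX and AOX, which raises it. A negative value there does not show that the shared response was lost. For AOX replicate 2 the cause was not tested.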

Other observations

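The permeases below were grouped after their values were seen. Of 25 measured amino acid and peptide permeases, 19 did not pass in NOX and 20 in AOX. Of the others, 3 rose in NOX, BAP2 by 1.05, GNP1 by 0.34 and ALP1, not well above background in control, by at least 1.63-fold, and 3 fell, PTR2 (-2.11), TAT1 (-0.83) and OPT2 (-0.56). In AOX, OPT2 (0.86), SAM3 (0.27) and BAP3, not well above background in control (at least 1.34-fold), rose, and DAL5 (-0.52) and TAT1 (-0.33) fell. The limma test of AOX against NOX called 7 as higher and 5 as lower in AOX, among them BAP2 at -1.20.

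The control probe sets for URA3, outside the main test, stood at -0.82, -0.52 and -0.82 in AOX and at -0.26, -0.25 and -0.32 in NOX relative to control. Poly-A controls averaged 6.78 on NOX replicate 1 and 6.97 on AOX replicate 1, against 7.24 to 7.34 on the other arrays.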
